A study of Mus musculus with 3 samples.

How the data were processed

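Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA bound to a chosen protein or histone mark and counts where in the genome it came from. Per the labels' protocols, small intestinal crypts were isolated from C57BL/6 mice carrying an Lgr5 allele that expresses a fluorescent protein and an inducible Cre recombinase. Crypt cells were fixed with formaldehyde and the chromatin was sheared by sonication before precipitation. The 3 libraries were 1 input library without antibody, 1 library precipitated with an antibody against Suz12 and 1 precipitated with an antibody against H3K27me3. There was 1 library per antibody, so no value below has a replicate error, and no p-value was computed across peaks, which are not replicates.

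The submitters' processing notes name Bowtie, MACS2 and the mouse build mm9, without versions, roles or parameters. The authors deposited 1 peak list for each antibody, and a peak list of the input library was not used here. Each peak has a chromosome, a start, an end, a name and a score. The lists themselves fit mm9: the last H3K27me3 peak on chromosome 1 ended at 197003005, and 1 of the peaks, on chromosome 4, ran 23 bp past the mm9 chromosome end. Whether peaks were called against the input is not given in the sources used here.

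What the deposited score measures is not given in the sources used here, and it was examined from its repeated values. With a tolerance of 0.01, 28.1% of H3K27me3 scores and 29.6% of Suz12 scores fell on the steps of the negative decimal logarithm of a Poisson probability with a background of 3.22 and 2.47 reads. Each background was the one, of many tried, that gave the most matches. Such widely spaced steps would match 2.19% of values by their density alone, which makes no allowance for that search. The best steps of a linear fold, found by the same search, matched 9.06% and 8.87%. The score is called the peak value below and was used to describe, rank or filter peaks within a list. The read depth behind each library is unknown, because the lists hold no read counts, so no floor for undetected peaks is given.

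Scores in both deposited lists began at 8, and no peak was narrower than 200 bp. Peak names carry running numbers with gaps. The Suz12 list held 1477 of 1735 numbers (85.1%) and the H3K27me3 list 25955 of 33967 (76.4%), so each is part of a longer numbered list. What the missing peaks were is not given in the sources used here. Sites with a value under 8 are not in any count below. Peaks within a list did not overlap.

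A Suz12 peak and an H3K27me3 peak were called overlapping when they shared at least 1 bp. Shares carry exact 95% binomial intervals (Clopper-Pearson), which cover counting error only and treat neighbouring peaks as independent. For chance overlap, the Suz12 peaks were placed 1000 times at random positions of their own chromosome with their widths kept. As an alternative, all Suz12 peaks of a chromosome were shifted together by 1 random distance, which keeps their spacing. Both used the whole chromosome length, with no account of where a peak could be called. Chance overlap may therefore be understated and the excess over it overstated. Medians of peak value and width were set beside those of 10000 random sets of peaks of equal number from the same list, as a description of these libraries. H3K27me3 peaks separated by at most 5000 bp were joined into domains. Chromosome lengths of mm9 came from GenomeInfoDb 1.38.1. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The overlap functions were tested on simulated data for the Suz12 and H3K27me3 comparison: of 600 peaks placed on H3K27me3 peaks and 400 placed off them, 600 were called overlapping.

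The comparisons, the rule for named regions and most alternatives were fixed before the data were examined. The regions named are the 10 Suz12 peaks with the highest value, the 10 longest H3K27me3 domains and the 5 domains with the most Suz12 peaks. Alternatives were a stricter or looser definition of overlap, the upper 50% of either list by value, joining gaps of 1000 and 10000 bp, width-matched random sets, and leaving out the sex chromosomes. Restriction to the autosomes and removal of the 10 longest domains were added after seeing the data. Comparisons of peaks with promoters and with gene lists had also been planned. They were not run, because the gene table at hand follows another build (GRCm38) and no mm9 annotation was used here. Regions are therefore named by mm9 coordinates, counted from 1, without gene, exon or intron.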

Results

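Polycomb repressive complex 2 (PRC2) is the enzyme complex that methylates histone H3 at lysine 27. Suz12 is a core subunit needed for its activity, and H3K27me3, the trimethylated product, marks repressed chromatin. Both were mapped in mouse small intestinal crypts, the epithelial pits that hold the stem and progenitor cells of the gut lining. The series asks where PRC2 and its mark lie in crypt cells. The data were 1 list of 1477 Suz12 peaks and 1 list of 25955 H3K27me3 peaks, each from 1 library.

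The Suz12 list was the shorter and covered less sequence. Suz12 peaks covered 1047 kb, or 0.0394% of mm9, and H3K27me3 peaks covered 14.6 Mb, or 0.551%. Individual Suz12 peaks were slightly wider, with a median of 421 bp (quartiles 274 and 792 bp) against 379 bp (quartiles 262 and 640 bp) for H3K27me3. The widest Suz12 peak measured 10243 bp and the widest H3K27me3 peak 7187 bp. Median peak values were 11.7 for Suz12 and 11.2 for H3K27me3, and the highest were 72.5 and 44.1. The 2 libraries may have been sequenced to different depths, so peak numbers, covered sequence and values were not compared between antibodies as amounts.

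The first comparison asked whether Suz12 sites carry the mark. Of the 1477 Suz12 peaks, 1423 overlapped an H3K27me3 peak, which is 96.3% (95% interval 95.3 to 97.2). Random placement gave a mean of 17.6 overlapping peaks (SD 4.10 over 1000 placements) and never more than 30. The observed number was 80.9-fold above that mean. When all peaks of a chromosome were shifted together, the most overlaps in 1000 shifts were 92. H3K27me3 peaks contained 90.0% of all sequence in Suz12 peaks, and 932 Suz12 peaks (63.1%) lay entirely within them.

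The 10 Suz12 peaks with the highest values all overlapped H3K27me3. The strongest lay on chromosome 11 at 21893201-21899193 (mm9), with a value of 72.5 and 90.9% of its 5993 bp under H3K27me3 peaks. Chromosome 2 followed with the peak at 18599304-18600567, which had a value of 65.1 and a single H3K27me3 peak over 90.3% of its length. The third, on chromosome 11 at 95867653-95870033, had a value of 61.4. A 6866 bp peak on chromosome 19 at 43685484-43692349 reached 60.9 and sat in an H3K27me3 domain of 66.8 kb with 9 Suz12 peaks. The peak on chromosome 2 at 74494125-74498161 had a value of 58.1 and lay in a 111 kb domain with 36 Suz12 peaks. Values of the remaining 5 ranged from 48.6 to 54.3. They lay on chromosome 7 at 138697844-138701742, chromosome 2 at 71381325-71385500, chromosome 11 at 102678856-102680116, and chromosome 4 at 114728422-114732233 and 99322549-99324055. H3K27me3 coverage among these 10 was lowest, at 67.2%, in the chromosome 11 peak at 102678856.

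Weak and strong Suz12 peaks overlapped H3K27me3 at rates whose intervals overlapped. In the lowest decile of Suz12 peaks by value, 95.9% overlapped (95% interval 91.4 to 98.5), and in the highest 94.6% did (89.6 to 97.6). The highest decile began at a value of 21.4. Its peaks without H3K27me3 included those with values of 29.6, 27.7, 24.2 and 23.3 more than 20 kb from any H3K27me3 peak. Mitochondrial peaks, with a median value of 22.7, were among them too. The far and mitochondrial peaks made up most of those without H3K27me3 in that decile, where 140 of 148 overlapped. The decile rates were not recomputed without them, so the rates cannot decide whether overlap depends on Suz12 value. The 54 Suz12 peaks without H3K27me3 were narrower, with a median of 295 bp against 428 bp for the 1423 with it. The latter median stood at percentile 98.8 of 10000 random sets. Median values were 10.6 without and 11.8 with H3K27me3. The latter, 11.75 before rounding, equalled the highest median of the random sets, and many sets tied with it. Its percentile of 75.1 therefore cannot decide whether the groups differed in value. The percentile was 99.9 both when at least 50% of the Suz12 peak had to be covered and with the upper 50% of H3K27me3 peaks by value. Of these 54 peaks, 33 had an H3K27me3 peak within 1000 bp. The group included all 6 peaks on the mitochondrial genome, all 4 on the Y chromosome and 2 of the 3 on the X. Whether peaks of this group are Suz12 sites or background was not tested.

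H3K27me3 peaks were common around Suz12 peaks out to 20 kb. At the centres of the 1464 autosomal Suz12 peaks, 91.1% of positions lay in an H3K27me3 peak. The share was 75.1% at 1 kb upstream in genome coordinates and 74.5% at 1 kb downstream. It was 49.7% and 48.0% at 5 kb, and 17.1% and 15.4% at 20 kb. Across all autosomal sequence, 0.591% lay in H3K27me3 peaks. Many Suz12 peaks are close neighbours, so these positions are not independent, and some may lie inside another Suz12 peak. The shares therefore do not measure how far H3K27me3 spreads from Suz12.

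**Figure D1:**
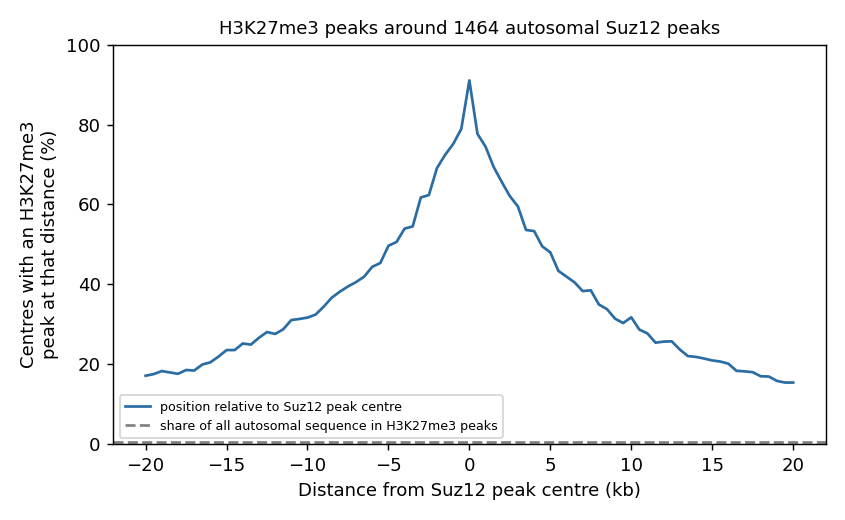
Share of 1464 autosomal Suz12 peak centres (vertical axis, %) that have an H3K27me3 peak at a given distance (horizontal axis, kb); the dashed line is the 0.591% of autosomal sequence in H3K27me3 peaks. The share was 91.1% at the centre and stayed at 15.4% or more out to 20 kb on either side.

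The reverse comparison asked how much of the mark coincides with detected Suz12. Of 25955 H3K27me3 peaks, 1222 overlapped a Suz12 peak, which is 4.71% (95% interval 4.45 to 4.97). By sequence, 6.44% of H3K27me3 peaks lay in Suz12 peaks. Random placement gave a mean of 21.8 and a maximum of 42 such peaks. The share was 7.78% when a Suz12 peak within 1000 bp sufficed and 8.44% among the upper 50% of H3K27me3 peaks by value. It was 2.96% when only the upper 50% of Suz12 peaks by value were used. A list of 1477 Suz12 peaks with a median width of 421 bp can reach few of 25955 H3K27me3 peaks. The share therefore does not show how much of the mark lacks Suz12.

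H3K27me3 peaks at Suz12 sites were wider and stronger than the rest. Their median width was 1317 bp (quartiles 691 and 2134 bp), 3.60-fold that of the 24733 peaks without Suz12, at 366 bp (259 and 598 bp). Median values were 20.5 (quartiles 15.4 and 25.7) and 11.1 (9.52 and 13.8). No median of the 10000 random sets exceeded 418 bp or a value of 11.7. Wider peaks have more chance to overlap and to reach a high value. In random sets matched on width by decile the median value was 16.2 and the highest was 16.9, still below 20.5. Widths inside a decile were not matched, and the widest decile reached 7187 bp. Part of the remaining difference may therefore still come from width. Suz12 was found at 0.385% of H3K27me3 peaks in the lowest decile by value (95% interval 0.185 to 0.707). This share was 7.55% (6.57 to 8.64) in the decile next to the top and 28.2% (26.4 to 29.9) in the top decile.

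**Figure D2:**
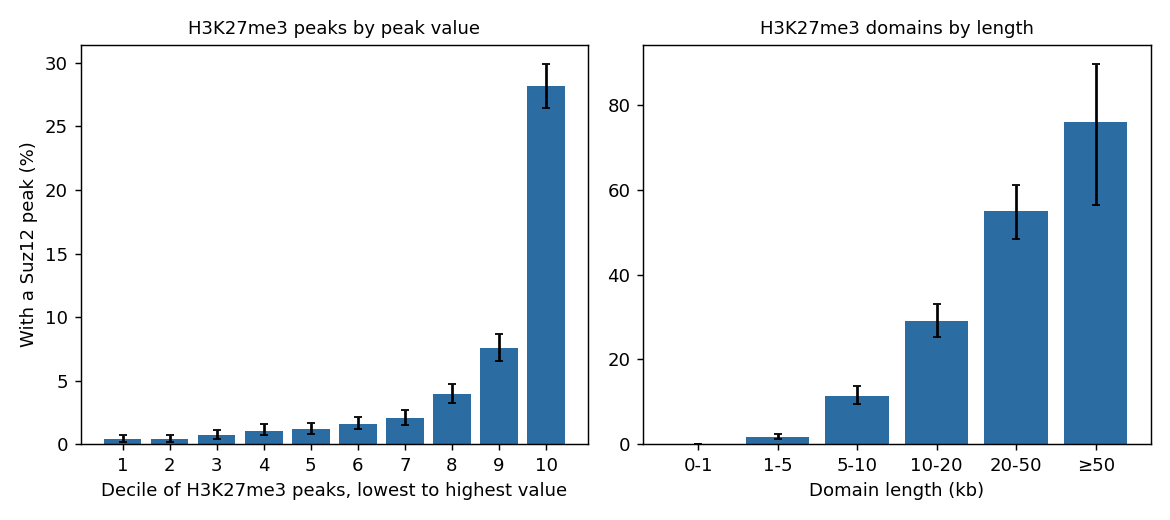
Share of H3K27me3 peaks, in deciles by peak value (left), and of H3K27me3 domains, by length in kb (right), that overlap a Suz12 peak (vertical axes, %); bars are shares and error bars exact 95% binomial intervals. The share rose from 0.385% to 28.2% across peak values, and was 75.9% in domains of 50 kb or more.

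Joining H3K27me3 peaks across gaps of at most 5000 bp gave 7663 domains with a median length of 1331 bp, of which 3457 consisted of a single peak. Suz12 peaks were present in 461 domains, 6.02% of the total (95% interval 5.49 to 6.57). Domains with Suz12 had a median length of 14132 bp and 10 H3K27me3 peaks, against 1078 bp and 2 peaks without. The share with Suz12 was 0.0282% (1 of 3544) below 1 kb and 11.5% (106 of 924) from 5 to 10 kb. It reached 54.9% (135 of 246) from 20 to 50 kb and 75.9% (22 of 29) from 50 kb upward. A gap of 1000 bp gave 12786 domains, and the upper 50% of H3K27me3 peaks by value gave 4912, with Suz12 in 9.47%.

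At a joining gap of 5000 bp, the 4 longest domains were also the 4 with the most Suz12 peaks. The longest, on chromosome 6 at 52094999-52276321 (mm9), spanned 181 kb and held 115 H3K27me3 and 51 Suz12 peaks. A domain of 172 kb on chromosome 15 at 102733526-102905392 held 122 and 25. On chromosome 11, the 112 kb from 96106630 to 96218807 held 80 and 23, and on chromosome 2 the 111 kb from 74481475 to 74592764 held 77 and 36. Together these 4 domains, 577 kb in all, contained 135 Suz12 peaks, or 9.14% of the list, and 1.52% of H3K27me3 peaks. The domain next in Suz12 number, on chromosome 14 at 122836734-122893973, also held 23 Suz12 peaks in 57.2 kb. The rank between it and the chromosome 11 domain was decided by length. Lengths, counts and ranks changed with the gap. At 1000 bp the most Suz12 peaks in a domain were 28, in 52.6 kb of chromosome 6. At 10000 bp the longest domain lay on chromosome 15 (255 kb).

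**Figure D3:**
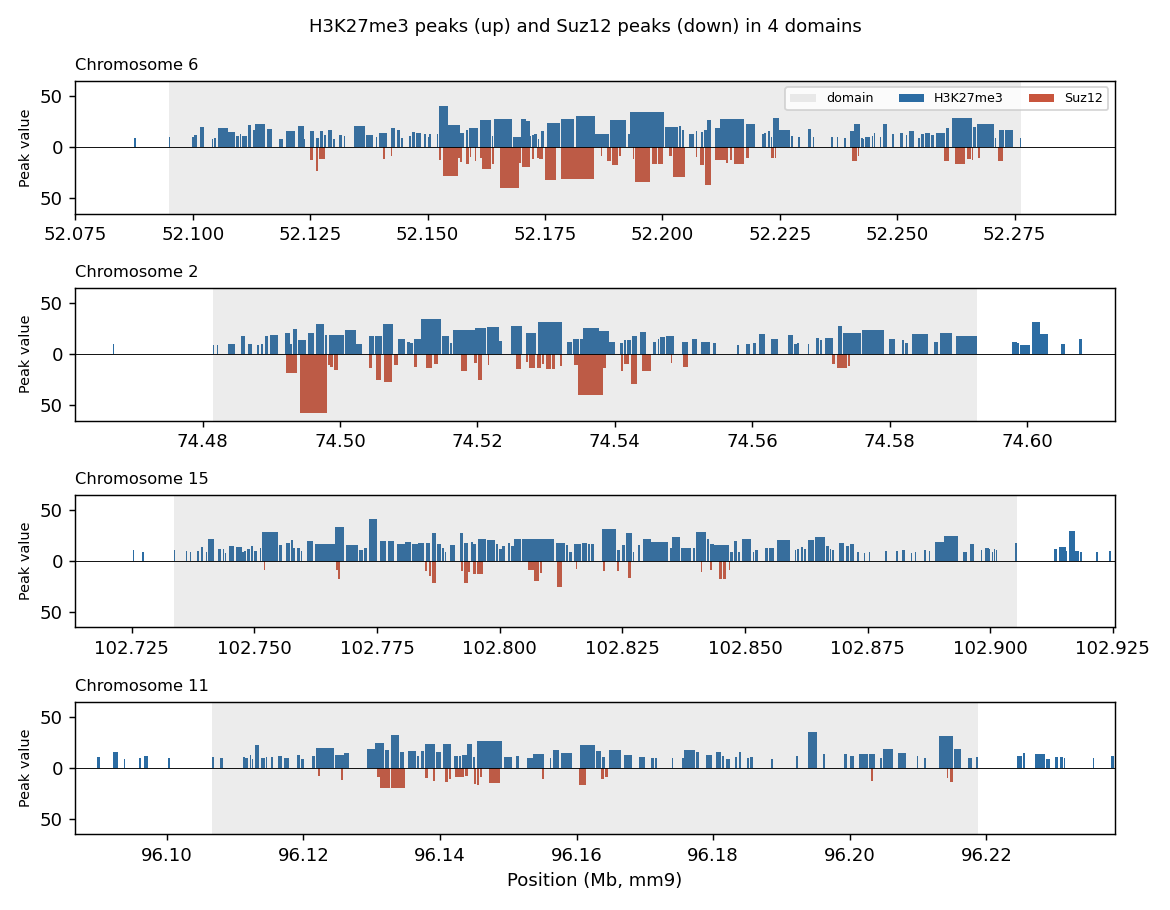
Maps to scale of the 4 domains with the most Suz12 peaks, with position in Mb (mm9) on the horizontal axis and peak value on the vertical axis; H3K27me3 peaks point up, Suz12 peaks point down, and grey marks the domain. Suz12 peaks number 51, 36, 25 and 23 on chromosomes 6, 2, 15 and 11.

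Other long domains differed widely in Suz12. A 105 kb domain on chromosome 7 at 52851186-52956119 held 81 H3K27me3 peaks and no Suz12 peak. Suz12 peaks were also not detected in a 75.1 kb domain on chromosome 11 at 117234393-117309462 or a 68.0 kb domain on the same chromosome at 85689679-85757659. A 75.4 kb domain on chromosome 1 at 138230733-138306118 held 2. On chromosome 5, the 76.2 kb domain at 28468162-28544382 held 8 and the 67.4 kb domain at 139981574-140048932 held 11. Of 275 domains of at least 20 kb, 118 (42.9%) held no Suz12 peak. That number rests on the joining gap and the peak list: it was 1 of 40 at 1000 bp, 310 of 521 at 10000 bp, and 29 of 128 (22.7%) with the upper 50% of H3K27me3 peaks by value.

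Both lists were unevenly spread over the chromosomes. Among the 19 autosomes, H3K27me3 peaks were densest on chromosome 11 (19.8 per Mb) and chromosome 19 (17.5 per Mb), and sparsest on chromosome 16 (4.27 per Mb). Among the autosomes, Suz12 peaks were densest on chromosomes 11 and 2, at 1.11 per Mb each, and sparsest on chromosome 18, at 0.154 per Mb. The X chromosome held 58 H3K27me3 peaks, or 0.348 per Mb, against 10.5 per Mb over the autosomes. The autosomal density was 30.1 times that of the X (95% counting interval 23.3 to 39.6), and 56.4 times when only the upper 50% of peaks by value were counted. X peaks also had lower values, with a median value of 10.4 against 11.2 and a highest value of 19.5. Suz12 had 3 peaks on the X, and its autosomal density was 32.9 times higher (95% counting interval 11.3 to 159.5).

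**Figure D4:**
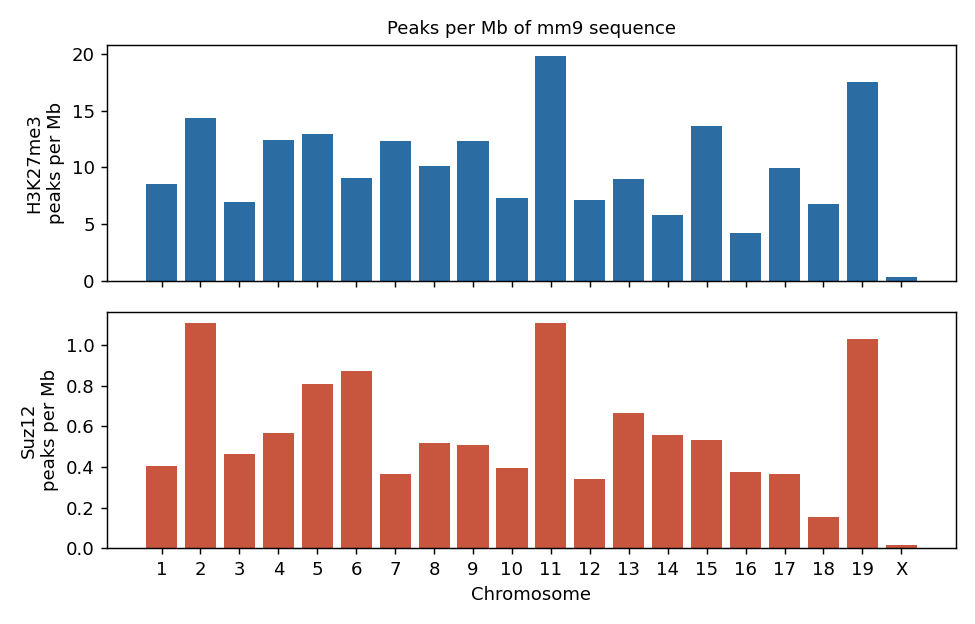
Peaks per Mb of mm9 sequence (vertical axes) for H3K27me3 (top) and Suz12 (bottom) on each autosome and the X chromosome (horizontal axis); each bar is 1 library's value. The X bars, at 0.348 and 0.0180 per Mb, lie below every autosome.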

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

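With 1 library per antibody, no replicate could be left out. No paired analysis was possible because each group has a single library. The share of Suz12 peaks overlapping H3K27me3 was 93.0% when at least 50% of the Suz12 peak had to be covered, 98.6% within 1000 bp and 92.8% with the upper 50% of H3K27me3 peaks by value. It stayed inside its 95% interval with the upper 50% of Suz12 peaks, without X and Y, and, added after seeing the data, on the autosomes alone. The share of H3K27me3 peaks overlapping Suz12 was 7.78% within 1000 bp, 8.44% for the upper 50% of H3K27me3 peaks and 2.96% for the upper 50% of Suz12 peaks. Against shifted rather than placed peaks, the excess over chance was 80.3-fold and 63.4-fold. At an overlap of 1 bp, the median value of Suz12 peaks with H3K27me3 (11.75) equalled the highest of the random sets. Many sets tied with it, so that setting cannot decide. This median lay above the central 95% of the sets, though not above every set, in 2 other settings. The difference was 1.52 when at least 50% had to be covered and 1.16 with the upper 50% of H3K27me3 peaks. Both settings put more peaks in the smaller group; the cause was not tested further. The number of domains was 12786 at a gap of 1000 bp and 4912 with the upper 50% of H3K27me3 peaks, and the share with Suz12 was 4.17% and 9.47%, or 7.08% at a gap of 10000 bp. The autosomal excess over the X was 56.4-fold for the upper 50% of H3K27me3 peaks. The higher H3K27me3 value at Suz12 sites stayed above the random sets with width matching by decile. The median at Suz12 sites exceeded theirs by 4.36, against 9.31 for unmatched sets, and width differences inside deciles may contribute. The difference in width from peaks without Suz12 fell from 951 to 542.5 bp within 1000 bp. Of the 32 alternatives, 18 left their result unchanged under the rule set for it, 12 moved it and 2 strengthened a difference. A reversed direction could be recorded only for the differences of medians, and none was. The minimum value of 8 in both lists limits what any of these counts can show about weaker sites, and the read depth is unknown.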

Other observations

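The tests of the minimum value and of gene number for the X, of domain length and of the Hox chromosomes were chosen only after the result was seen; that of a single X copy was set down before its value was computed. The test of weak Suz12 sites was also set down before its value was computed, but it replaced a comparison of highest H3K27me3 values whose result had been seen and could not separate the explanations.

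On the autosomes, 8 of the 42 Suz12 peaks without H3K27me3 lay more than 20 kb from any H3K27me3 peak. Of these, 3 fell within 5.73 kb of chromosome 17 (39980054-39985779, mm9), with values of 17.2 to 29.6, and 2 within 4.61 kb of chromosome 2 (98502584-98507190), with values of 9.58 and 18.6. The other 3 stood alone, on chromosome 5 at 147072594-147072862 (value 27.7), chromosome 11 at 108872977-108873391 (23.3) and chromosome 15 at 35227897-35228149 (10.3). These peaks were singled out after their values were seen, and clustering was not tested. The mitochondrial genome carried 6 Suz12 peaks over 37.5% of its length, with values of 10.1 to 26.9 and no H3K27me3 peak. The Y chromosome carried 4 Suz12 peaks between 2782219 and 2888981, with values of 10.1 to 15.3, and no H3K27me3 peak. Nothing from the input library was used, so whether any peak in this paragraph reflects Suz12 binding or background was not tested. They are therefore no evidence of Suz12 binding without the mark.

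H3K27me3 peaks were scarce on the X chromosome. The minimum of the deposited list is not the main cause, since 58 of the 85 peak numbers on the X (68.2%) were still present, against 76.4% on the autosomes, and a low number of genes is not either, since the X had 0.0600 H3K27me3 peaks per protein-coding gene and the lowest autosome 0.619. A candidate explanation is a single copy of the X in the sampled cells, as in male mice, whose sex the labels do not give. Reads were estimated on the Poisson scale with 1 background of 3.22 reads for every H3K27me3 peak. Only 28.1% of scores fell on the steps of that scale, so the read numbers are an assumption for the rest. An X site with 50% of the reads would reach the minimum value's 18 reads where its autosomal counterpart had 36, a value of 25.7. The autosomes held 0.264 such peaks per Mb, and the X density was 1.32 times that (95% counting interval of the X count 1.00 to 1.70). Most weaker X sites would then have been lost before peaks were numbered, at a caller threshold that is not given, and this part was not tested. Only the number of X peaks was compared. Whether their values, at most 19.5, are those a single copy would give was not tested. For Suz12 the same reasoning gave 8.22 X peaks and only 3 were found, so the match was not repeated there. Other explanations stay open.

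Most H3K27me3 domains held no Suz12 peak. A list of 1477 Suz12 peaks could not reach most of 7663 domains, so the list length alone fixes that majority. One explanation is that weak Suz12 sites fell under the minimum value of the Suz12 list. Among long domains (at least 20 kb) with Suz12, the 78 with the lower highest H3K27me3 values had a median Suz12 value of 11.8 against 13.3 in the other 79, just below the 11.9 to 13.2 that held 95% of 10000 random divisions, a marginal result that is consistent with weakly marked domains having Suz12 nearer the minimum. A true difference in Suz12 between domains stays open: the 118 long domains without it were shorter (median 26526 against 30524 bp), had fewer H3K27me3 peaks (16 against 21) and lower highest values (22.1 against 28.6), though 14 of them reached 28.6. Whether shortness of the domains alone accounts for the pattern could not be decided, because the share of long domains without Suz12 was 42.9% (118 of 275) at a gap of 5000 bp, 59.5% (310 of 521) at 10000 bp and 22.7% (29 of 128) with the upper 50% of H3K27me3 peaks, but 1 of 40 at 1000 bp.

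A hypothesis is that the 4 domains cover the Hox gene clusters, that is, that the domains with the most Suz12 peaks may hold these genes, which encode the homeobox factors of body axis patterning and are classical PRC2 targets. The gene table of build GRCm38 lists the Hoxa genes on chromosome 6, Hoxb on 11, Hoxc on 15 and Hoxd on 2, and all 4 domains lay on these chromosomes, 1 on each. The chromosomes prompted the hypothesis, so this match is no independent test of it. The same held at a joining gap of 10000 bp, but at 1000 bp 3 of the 4 lay on these chromosomes. Positions were not compared between builds, and the hypothesis stays open.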
